A study of Mus musculus with 8 samples.

How the data were processed

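RNA was measured by sequencing of stranded poly(A) libraries (TruSeq Stranded mRNA LT, Illumina) from wild-type mouse embryonic fibroblasts, connective tissue cells grown in culture. There were 8 libraries in 4 groups of 2: control, SRT1720 (0.2 µM), RSL3 (1 µM for 2 h) and SRT1720 given 30 min before RSL3. RSL3 is an inhibitor of GPX4 that is used to induce ferroptosis, a death of cells by lipid peroxidation, and SRT1720 is sold as an activator of SIRT1. The deposited table held expected counts, that is estimated read counts in which reads shared between genes had been divided, for 17910 genes with NCBI Gene IDs and symbols. Between 76.6% and 77.7% of the values of a library, zeros included, were exactly whole numbers. The aligner, the counting tool, the genome build and any filter applied by the authors are not given in the sources used here. The extraction text in the labels also names human HT1080 cells and lung homogenates, which are not among these samples. The columns were taken as replicates 1 and 2 of each group by the library names in the labels, in which a bare name is replicate 1 and a name with a suffix is replicate 2. Apart from the RSL3 group those names are spelled differently from the column names. The numbers affect no comparison of groups. They enter the alternatives with a replicate block, the names of left-out libraries, the omission of both libraries numbered 2, the correlation of deviations between groups and the signs of differences between the libraries of a pair.

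Counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1). Library composition was scaled by TMM, filterByExpr with the group design kept 12618 genes, and 705 genes were at 0 in all libraries. A quasi-likelihood model with a mean for each of the 4 groups and no other covariate (glmQLFit without the robust option) was fitted to all 8 libraries, so that the groups share an estimate of the spread. It had 4 residual degrees of freedom and 5.73 prior degrees of freedom. The common dispersion was 0.0112, which is a coefficient of variation of 10.6% between libraries of a group. The test is two-sided, and p-values were adjusted over the 12618 genes of a comparison by the Benjamini-Hochberg method with a threshold of 0.05. The comparisons were RSL3 with control, SRT1720 with control, SRT1720 plus RSL3 with each of RSL3, SRT1720 and control, and the interaction. The interaction is the effect of SRT1720 in RSL3-treated cells minus its effect in cells without RSL3. Levels are TMM-scaled CPM (counts scaled to a common library total), as mean ± SD over the 2 libraries of a group. Log2 fold changes are given ± SE, where the SE is the log2 fold change divided by the square root of the F statistic. Depth was 20579122 to 21287620 counts per library.

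The comparisons, the 29 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The lists were ferroptosis drivers, ferroptosis suppressors, NRF2 targets, ATF4 and integrated stress response, ER unfolded protein response, immediate early genes, heat shock response, metallothioneins and metal response, iron handling, fatty acid oxidation, PPAR and PGC-1 regulators and targets, fatty acid synthesis, fatty acid activation and phospholipid remodelling, cholesterol and mevalonate synthesis, FOXO family and targets, sirtuins and NAD metabolism, extracellular matrix and myofibroblast genes, NF-kB and inflammatory genes, p53 targets, cell cycle, mitochondrially encoded genes, YAP and TEAD targets, hypoxia and glycolysis, and markers of macrophages, endothelium, epithelium, neural cells, muscle, and adipocytes and chondrocytes. Mitochondrially encoded genes have no entry in the table, so that list was not analysed here. Lists were tested with camera, which compares the genes of a list with all others, at a preset correlation between genes of 0.01 and again with the correlation estimated from the data. Lists with under 5 tested members are given as values. The named genes of each comparison were the 8 with the largest rise and the 8 with the largest fall among those past the threshold, with a mean of at least 5 CPM and no overlap between the libraries compared (for the interaction, only past the threshold). Predicted loci were skipped. To these were added up to 4 members of each list with the smallest p among those that passed, or the member with the smallest p where none passed, and 10 genes in every comparison: Gpx4, Sirt1, Foxo3, Acsl4, Slc7a11, Hmox1, Chac1, Ptgs2, Cpt1a and Scd1. Another 6 lists were chosen after the data had been seen. They included aryl hydrocarbon receptor targets, interferon-stimulated genes, actin cytoskeleton genes, proteasome subunits and zinc finger genes with Zfp symbols. The remaining list and some single genes that the rule names are not reported here.

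The alternatives were size factors RLE, library size only, no low-count filter, a replicate block, limma-voom, DESeq2 1.42.0, the 4 libraries compared on their own, each library left out in turn, the estimated correlation for lists, and a minimum of 1.5-fold for the comparison of RSL3 effects. Removal of trends on GC content and transcript length, a replicate block with the SRT1720 plus RSL3 numbers exchanged, and omission of both the control and the RSL3 library numbered 2 were chosen after the data had been seen. The effect of RSL3 with and without SRT1720 was set against 20 simulated data sets with additive effects, and its reversal against 20 in which SRT1720 had no effect in RSL3-treated cells and kept its fitted effect in cells without RSL3. Simulated counts were drawn for each gene alone, with the same spread in all groups, and hold no deviations shared between the genes of a library. Exon number, transcript length, GC content and neighbouring genes came from GENCODE M21 and RefSeq annotations of GRCm38, matched by gene for 97.2% of the table. Positions are not given because the build behind the counts is not known. In tests on simulated data at the sizes of the RSL3 comparison, only genes with a mean count above 20 were altered. A change of 1.5-fold was recovered in 48% of altered genes, 2-fold in 86%, 4-fold in 98% and 8-fold in 100%. Among the unaltered ones of the 12618 genes there were 14 false calls. Recovery of genes with lower counts was not tested. The altered list was called, and 0 of 20 unaltered lists were called by camera. These lists held random genes simulated without correlation between them. The estimated correlation of the matrix list in the RSL3 comparison was 0.408, so the 0 of 20 says nothing about false calls in such lists. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.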

Results

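RNA of mouse embryonic fibroblasts was counted in 4 groups of 2 libraries. The libraries held 20908830 and 20959586 counts in control cells, 20579122 and 21072727 in SRT1720 cells, 21074701 and 21137819 in RSL3 cells, and 21287620 and 21261602 in cells given SRT1720 and then RSL3. RSL3 set the libraries apart along the first principal component, which held 68.7% of the variance. The gene with the largest share of the counts was Eef1a1, a translation elongation factor, in the 4 libraries without RSL3 (1.19% to 1.29%). Heat shock genes took 1.41% to 1.49% of the counts without RSL3 and 3.31% to 4.14% with it. The groups differed in how alike their libraries were, with an SD of the log2 difference between the pair of 0.21 in control, 0.136 in SRT1720, 0.275 in RSL3 and 0.146 in SRT1720 plus RSL3 cells over 5590 genes. These differences exceeded counting error, with a chi-square per degree of freedom of 13.92 to 57.85. Across these genes, which are not independent replicates, the deviations of the control pair correlated with those of the RSL3 pair (r = 0.76), and those of the SRT1720 plus RSL3 pair correlated negatively with both (r = -0.32 with control and -0.43 with RSL3), while r was 0, 0 and -0.02 between the SRT1720 pair and the control, RSL3 and SRT1720 plus RSL3 pairs. The difference within a pair also followed GC content, with a Spearman rho of -0.43 in control, 0.18 in SRT1720, -0.53 in RSL3 and 0.42 in SRT1720 plus RSL3 cells. With transcript length rho was 0.25, 0.09, 0.31 and -0.62. The labels do not say whether replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical.

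RSL3 inhibits GPX4, the enzyme that reduces lipid hydroperoxides, and the comparison of RSL3 with control asks what 2 h of it changed. Hmox1 (NCBI Gene ID 15368), the heme-degrading oxygenase, went from 103.9 ± 49.5 to 8393 ± 531 CPM (SD, n = 2), a log2 fold change of 6.34 ± 0.30 (adjusted p = 4.89e-07). Chac1 (69065), which degrades glutathione, went from 15.3 ± 0.632 to 961.3 ± 76.0 CPM (5.97 ± 0.13, adjusted p = 5.79e-09). The inducible chaperone gene Hspa1b (15511) went from 90.95 ± 12.2 to 6629 ± 929 CPM (6.19 ± 0.27). Slc7a11 (26570), the cystine transporter subunit, went from 6.66 ± 1.34 to 92.1 ± 3.53 CPM (3.79 ± 0.17, adjusted p = 3.13e-07), and Ptgs2 (19225), which encodes the inducible cyclooxygenase, from 180.3 ± 6.29 to 1527 ± 275 CPM (3.08 ± 0.14, adjusted p = 4.08e-07). Of 12618 genes tested, 2308 rose and 2203 fell (35.8%), and 753 rose and 649 fell by 2-fold or more. With library size only, 1220 rose and 4675 fell, because that scaling moves all values of this comparison by -0.28 on the log2 scale. Directions below are those after TMM scaling.

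Among the heat shock genes, 22 of 23 rose after RSL3 and 0 fell in edgeR (23 rose adjusted over the list alone, median log2 change 1.37), among them the chaperones Hspa1a (7.13 ± 0.23), Dnajb4 (2.54) and Hsp90aa1 (1.60 ± 0.09). Hspa1a and Hspa1b are nearly identical in sequence, so the division of reads between them is uncertain. The list's median was 0.29 lower in the second RSL3 library than in the first. Of 41 targets of ATF4, the transcription factor of the integrated stress response, 37 rose (39 adjusted over the list alone, median 1.33), with the transcription factor Atf3 at 6.21 ± 0.12, the mTORC1 inhibitor Ddit4 at 4.81 ± 0.13 and the phosphatase subunit Ppp1r15a at 3.59 ± 0.12. Of 31 targets of NRF2, the regulator of antioxidant genes, 22 rose (24 adjusted over the list alone, median 0.80), including Srxn1 (2.53 ± 0.10) and Gclc (1.92 ± 0.17). Of 40 immediate early genes, 33 rose and 3 fell (the same counts adjusted over the list alone, median 1.94), with the transcription factor Klf4 at 3.75 ± 0.10 and the mRNA-decay factor Zfp36 at 4.21 ± 0.12. In the unfolded protein response of the endoplasmic reticulum, 14 of 22 genes rose (14 adjusted over the list alone, median 0.44), with Herpud1 at 3.28 ± 0.12 and the chaperone Hspa5 at 1.75 ± 0.17. That list passed with the preset correlation, and its adjusted p was 0.272 with an estimated correlation. Of 5 metallothionein and metal-response genes, 4 rose and the zinc importer Slc39a10 fell (-1.27). Mt1 was at 3.34 ± 0.21 and Mt2 at 3.32 ± 0.28, and the list's adjusted p was 0.0752 with an estimated correlation. Its median was 0.39 lower in the second RSL3 library than in the first.

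Hypoxia and glycolysis genes rose as a group after RSL3, 26 of 29 (26 up and 2 down adjusted over the list alone, median 0.96). Vegfa (22339), the vascular growth factor, went from 99.9 ± 5.03 to 1033 ± 145 CPM (3.37 ± 0.12), Bnip3 (12176), a mitophagy receptor, from 12.35 ± 0.263 to 119.9 ± 3.47 CPM (3.28 ± 0.11), and the glucose transporter gene Slc2a1 from 74.75 ± 5.41 to 411.6 ± 40.2 CPM (2.46 ± 0.11). Of 32 FOXO family members and targets, 20 rose and 1 fell (20 and 2 adjusted over the list alone, median 0.58). Foxo3 itself (56484), a forkhead transcription factor, went from 41.2 ± 3.41 to 184.1 ± 24.6 CPM (2.16 ± 0.13, adjusted p = 1.98e-06). Its targets Ccng2 and Gadd45a were at 4.15 ± 0.19 and 3.66 ± 0.13. Sirt1 (93759), an NAD-dependent deacetylase, went from 28.35 ± 1.80 to 105.0 ± 15.0 CPM (1.89 ± 0.13, adjusted p = 5.95e-06). In the list of sirtuins and NAD metabolism 6 of 21 genes rose and 2 fell (the same adjusted over the list alone), with Nampt at 1.60 ± 0.13 and Sirt7 at -0.87 ± 0.15. That list did not pass (adjusted p = 0.567), and its median (-0.15) differed in sign from its mean (0.15) and its test. Of 26 genes of cholesterol and mevalonate synthesis, 15 rose (15 up and 2 down adjusted over the list alone, median 0.48), with the sterol-regulated gene Insig1 at 3.45 ± 0.11. Of 23 p53 targets 13 rose and 6 fell (13 and 7 adjusted over the list alone, median 0.56), with the cell cycle inhibitor Cdkn1a at 3.21 ± 0.13 and Sesn2 at 3.36 ± 0.14.

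Ferroptosis suppressors rose as a list after RSL3, 16 of 31 up and 1 down (17 and 2 adjusted over the list alone, median 0.77). They included the autophagy receptor Sqstm1 (2.91 ± 0.10) and the amino acid transporter subunit Slc3a2 (1.75 ± 0.10). Sqstm1 is also on the NRF2 list and Slc3a2 on the ATF4 list. Gpx4 (625249) did not pass, with 305.6 ± 29.8 CPM in control and 373.5 ± 52.1 CPM in RSL3 cells (0.29 ± 0.12, adjusted p = 0.0907). It passed without RSL3 replicate 2 (0.42), with the crossed replicate block (0.29) and without both libraries numbered 2 of control and RSL3 (0.33). Of 25 ferroptosis drivers 8 rose and 1 fell (the same adjusted over the list alone), with the polyamine acetyltransferase Sat1 at 2.40 ± 0.10 and the transcription repressor Bach1 at 1.37 ± 0.16. The drivers' median was 0.09, or -0.19 with library size only, and the list's adjusted p was 0.201 with an estimated correlation. Its call also ended without control replicate 1 (0.05) and without RSL3 replicate 2 (0.10). Acsl4 (50790), which activates polyunsaturated fatty acids, passed in this comparison at 0.38 ± 0.12 (adjusted p = 0.0389, 43.2 ± 3.29 and 56.1 ± 7.37 CPM). Its call ended with library size only (0.09), without control replicates 1 (0.30) or 2 (0.46), RSL3 replicate 2 (0.23), SRT1720 replicates 1 (0.38) or 2 (0.37), and SRT1720 plus RSL3 replicates 1 (0.36) or 2 (0.38). The call of Acsl4 also ended in the 4 libraries compared on their own (0.357) and without both libraries numbered 2 of control and RSL3 (0.315). Of 23 iron-handling genes 5 rose and 1 fell (the same adjusted over the list alone), including the ferritin genes Fth1 (0.85 ± 0.16) and Ftl1 (1.13 ± 0.16). That list did not pass (adjusted p = 0.175), and its median of 0.16 was -0.13 with library size only.

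The lists of fatty acid genes did not pass after RSL3, while single members did. In fatty acid oxidation 1 of 35 genes rose and 8 fell (1 and 7 adjusted over the list alone, median -0.07, adjusted p = 0.23). The carnitine acyltransferase Cpt2 was at -1.40 ± 0.15. Cpt1a (12894) was at 32.5 ± 5.23 CPM in control and 31.3 ± 4.15 CPM in RSL3 cells (-0.06 ± 0.14, adjusted p = 0.794). In fatty acid synthesis, elongation and desaturation 7 of 29 genes rose and 2 fell (the same adjusted over the list alone, adjusted p = 0.381), with the elongase Elovl3 at 2.43 ± 0.29. Its median of 0.21 was -0.08 with library size only. Scd1 (20249), the stearoyl-CoA desaturase, was at 135.4 ± 18.5 and 145.4 ± 18.4 CPM (0.10 ± 0.13, adjusted p = 0.575). In fatty acid activation and phospholipid remodelling 10 of 40 genes rose and 5 fell (the same adjusted over the list alone, adjusted p = 0.567), with Acsl3 at 1.05 ± 0.11 and the lipin Lpin1 at 1.54. Its median of 0.04 was -0.24 with library size only. Of 13 PPAR and PGC-1 genes 3 rose (the same adjusted over the list alone, adjusted p = 0.211), including the thioesterase Acot2 at 1.19.

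Cell cycle genes were lower as a list after RSL3, with 22 of 39 down and 10 up (22 and 11 adjusted over the list alone, median -0.46), and its adjusted p was 0.213 with an estimated correlation. The mitotic kinases Plk1 (-2.04 ± 0.14) and Aurka (-1.22 ± 0.11) and cyclin D1 (Ccnd1, -1.42 ± 0.11) fell. The largest falls were those of the mitotic histone kinase Haspin (-3.96 ± 0.20, adjusted p = 7.48e-07), the histone gene H2ac24 (162.8 ± 13.9 to 13.2 ± 0.607 CPM, -3.63 ± 0.14), the sulfotransferase Chst12 (-3.31 ± 0.19) and the helicase Pif1 (-3.12 ± 0.19). Of 19 targets of YAP and TEAD 8 fell and 2 rose (the same adjusted over the list alone, median -0.24), with the matricellular genes Ccn1 (16007; -1.25 ± 0.10) and Ccn2 (-0.76 ± 0.12) lower. The adjusted p of this list was 0.402 with an estimated correlation, and its call ended without RSL3 replicate 1 (-0.12). Of 45 extracellular matrix and myofibroblast genes 10 rose and 1 fell (the same adjusted over the list alone, adjusted p = 0.249), with the metalloproteinase inhibitor Timp3 at 0.76 ± 0.11. The list's median of 0.28 was -0.01 with library size only. It was also 0.26 higher in the second control library than in the first and 0.35 higher in the second RSL3 library than in the first. Of 27 NF-kB and inflammatory genes 4 rose and 7 fell (the same adjusted over the list alone, median -0.06, adjusted p = 0.6), with Irf1 at -1.81 ± 0.19 and Tnfaip3 at -1.39 ± 0.17. This list was 0.56 lower in the second control library than in the first and 0.48 lower in the second RSL3 library than in the first.

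Markers of other cell types were few among the genes tested in the RSL3 comparison. All 3 macrophage markers rose (Cd14 0.475, Cd68 1.78 and Csf1r 1.49), as did 1 of 3 endothelial markers (Kdr, 2.10), 1 of 3 muscle markers (Acta1, 0.75), and 1 of 4 markers of adipocytes and chondrocytes (Sox9, 2.42). Of 4 neural markers Tubb3 rose (0.97) and Nes fell (-0.51), and of 3 epithelial markers 0 passed in edgeR, with Grhl2 at 1.10 (adjusted p = 0.12). Adjusted over the list alone these counts were the same. The call of Acta1 ended without both libraries numbered 2 of control and RSL3 (0.68). The calls of Cd14 and Acta1 ended with library size only (0.19 and 0.46) and with DESeq2 (0.47 and 0.74). In the 4 libraries compared on their own both calls ended as well (0.46 and 0.73). They also ended without control replicate 2 (0.38 and 0.55), RSL3 replicate 1 (0.27 and 0.59), SRT1720 replicate 1 (0.47 and 0.75), SRT1720 replicate 2 (0.47 and 0.75), SRT1720 plus RSL3 replicate 1 (0.46 and 0.73) or its replicate 2 (0.47 and 0.75), and that of Cd14 without control replicate 1 (0.57). With camera at the preset correlation, 64 list results over all comparisons passed, and 30 of them held with an estimated correlation. In the RSL3 comparison those that held were the lists of suppressors, NRF2, ATF4, immediate early, heat shock, cholesterol, FOXO, p53 and hypoxia genes. Their adjusted p with an estimated correlation lay between 0.00408 and 0.0277.

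**Figure D1:**
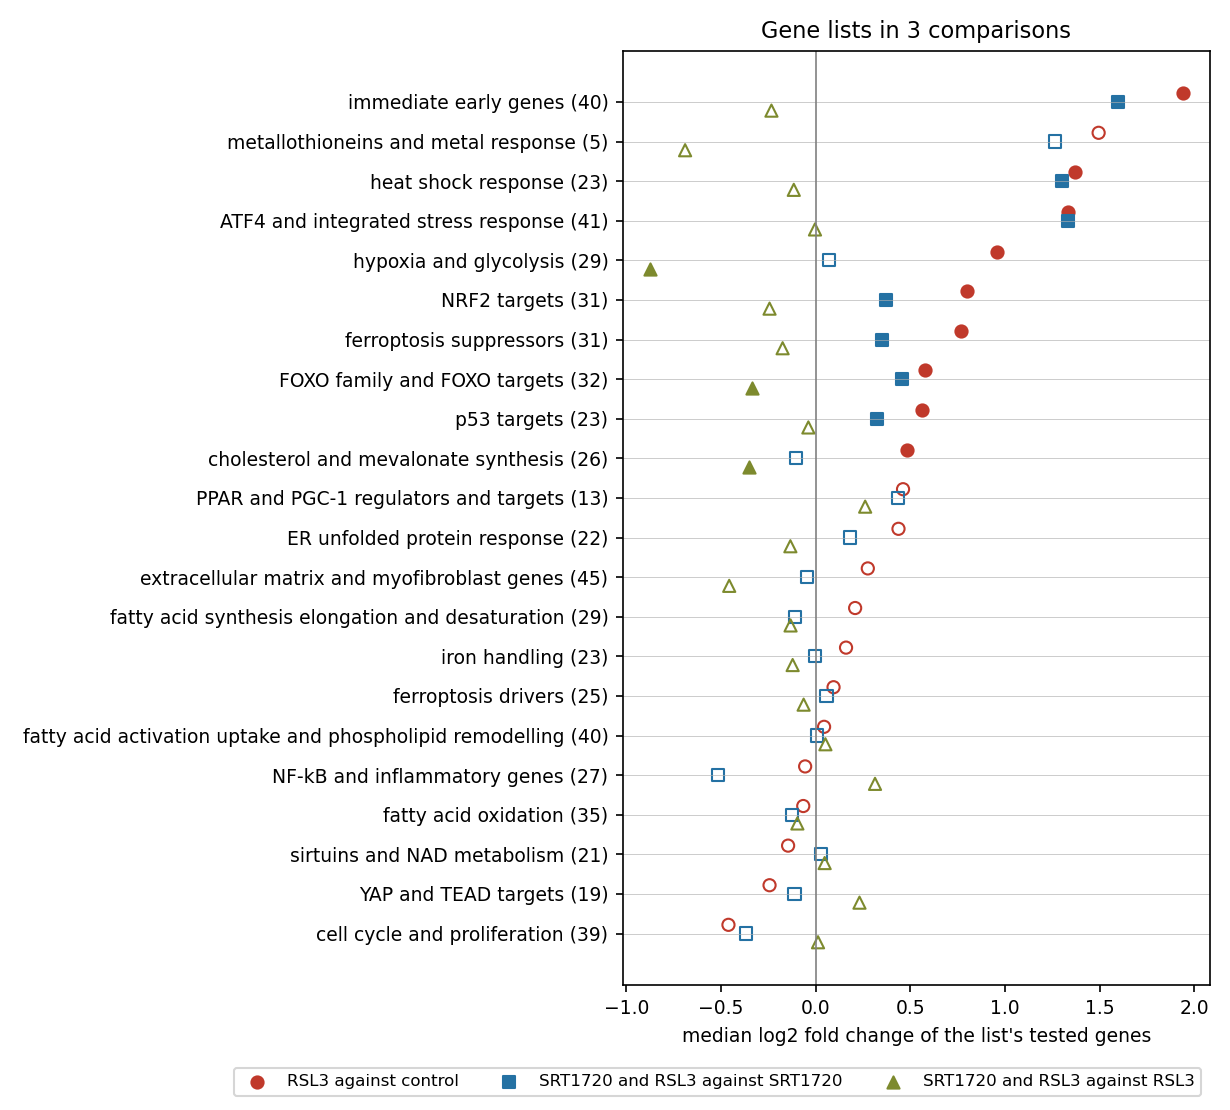
Median log2 fold change of each gene list with at least 5 tested members (x axis), for RSL3 against control (circles), SRT1720 plus RSL3 against SRT1720 (squares) and SRT1720 plus RSL3 against RSL3 (triangles), with 2 libraries per group; filled symbols passed an adjusted p of 0.05 with an estimated correlation. The hypoxia median was 0.96 after RSL3 alone and 0.07 (-0.14 with library size only) after RSL3 in SRT1720 cells, and the ATF4 medians were 1.33 and 1.33.

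SRT1720 is sold as an activator of SIRT1, and its comparison with control asks what it changed without RSL3. Few genes passed, among them the regulators of signalling Rgs16 and Dusp4. Rgs16 went from 104.3 ± 0.473 to 309.0 ± 2.98 CPM (SD, n = 2; 1.57 ± 0.10, adjusted p = 0.000193), the phosphatase gene Dusp4 from 15.0 ± 0.730 to 46.1 ± 2.55 CPM (1.62 ± 0.14, adjusted p = 0.00116) and Vegfa from 99.9 ± 5.03 to 272.7 ± 13.8 CPM (1.45 ± 0.11, adjusted p = 0.000471). Ptx3, a secreted pentraxin, fell from 71.97 ± 3.16 to 22.8 ± 0.290 CPM (-1.66 ± 0.11, adjusted p = 0.000193), and Tiparp, a mono-ADP-ribosyltransferase, from 68.5 ± 2.16 to 25.5 ± 2.00 CPM (-1.43 ± 0.11, adjusted p = 0.00045). Of 12618 genes, 139 rose and 26 fell (1.3%), of which 44 and 11 changed by 2-fold or more. With library size only 114 rose and 26 fell. The largest rise was that of the collagenase Mmp13 (3.59 ± 0.44, adjusted p = 0.00706), whose call ended without SRT1720 replicate 1 (3.53) or 2 (3.64). The activin subunit gene Inhbb (-1.81 ± 0.16, adjusted p = 0.00146) and Txnip (-1.72 ± 0.20, adjusted p = 0.00555) fell. The call of Inhbb ended without SRT1720 replicate 1 (-1.70) and that of Txnip without SRT1720 replicate 2 (-1.48). Of the named genes that passed, only Rgs16, Dusp4, Vegfa, Ptx3 and Tiparp kept their call under all alternatives run. The number of genes called was 30 without control replicate 2, 10 without SRT1720 replicate 1, 9 without SRT1720 replicate 2, 56 and 60 without SRT1720 plus RSL3 replicates 1 and 2, and 502 and 511 without RSL3 replicates 1 and 2.

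Sirt1 was at 27.2 ± 0.0536 CPM with SRT1720 (-0.06 ± 0.13, adjusted p = 0.877) and Foxo3 at 45.4 ± 0.424 CPM (0.14 ± 0.12, adjusted p = 0.679), and neither passed. Chac1 rose to 32.2 ± 2.45 CPM (1.07 ± 0.11, adjusted p = 0.00327) and Ptgs2 to 341.7 ± 11.7 CPM (0.92 ± 0.13, adjusted p = 0.0119). Without SRT1720 replicate 1 both calls ended (0.99 and 0.89), and that of Ptgs2 also ended without SRT1720 replicate 2 (0.96) or control replicate 2 (0.89). Gpx4 (0.23), Hmox1 (0.42), Slc7a11 (0.59), Acsl4 (0.13), Cpt1a (-0.18) and Scd1 (-0.05) did not pass. Hmox1 passed without control replicate 2 (1.01) and was at -0.006 without control replicate 1, and Scd1 (0.10) and Sirt1 (0.005) turned in direction without control replicate 2. Slc7a11 passed with GC and length trends removed (0.62) and, like Hmox1 (1.01), without both libraries numbered 2 of control and RSL3 (0.81). Immediate early genes (9 of 40 up, 15 up and 1 down adjusted over the list alone, median 0.27), hypoxia genes (3 of 29 up, 6 adjusted over the list alone, median 0.11) and cholesterol genes (4 of 26 up, 7 adjusted over the list alone, median 0.17) were higher as lists, each with adjusted p = 0.0748 with an estimated correlation. NF-kB genes were also higher (3 of 27 up, 10 adjusted over the list alone, median 0.52), as were p53 targets (2 of 23 up, 3 adjusted over the list alone, median 0.14) and metallothionein genes (1 of 5 up, 2 up and 1 down adjusted over the list alone, median 0.19), each with adjusted p = 0.221 with an estimated correlation. ATF4 targets were higher (3 of 41 up, 7 adjusted over the list alone, median 0.15, adjusted p = 0.305 with an estimated correlation), and so were unfolded protein response genes (1 of 22 up, 5 adjusted over the list alone, median 0.15, adjusted p = 0.291 with an estimated correlation). Extracellular matrix genes were lower (2 of 45 down and 1 up, 5 and 3 adjusted over the list alone, median -0.16, adjusted p = 0.499 with an estimated correlation). The lists of fatty acid oxidation (median -0.10, adjusted p = 0.28 with an estimated correlation) and cell cycle genes (median -0.08, adjusted p = 0.291 with an estimated correlation) were also lower, with 0 members past the threshold in edgeR for either. None of the 11 calls held with an estimated correlation. Without control replicate 1 the calls of ATF4 (0.02), metallothionein (0.06), fatty acid oxidation (-0.10) and cell cycle genes (-0.08) ended, without control replicate 2 those of matrix genes (-0.04) and p53 targets (0.07), and without SRT1720 replicate 1 those of fatty acid oxidation (-0.12) and cell cycle genes (-0.06). Matrix and NF-kB genes differed by 0.06 and -0.03 between the SRT1720 libraries and by 0.26 and -0.56 between the control libraries.

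The other lists did not pass with SRT1720. Ferroptosis drivers had 2 members up, suppressors 1, NRF2 targets 1 and iron handling 1, and FOXO genes had 2 up and 1 down (4 and 1 adjusted over the list alone). The suppressors' median (-0.05) differed in sign from their mean (0.04) and test. Heat shock, PPAR, fatty acid synthesis, fatty acid activation, sirtuin and YAP lists had 0 members past the threshold in edgeR, where 1672 genes had an unadjusted p under 0.05 and DESeq2 called 384. Among the sirtuin list 1 gene passed adjusted over the list alone, and among YAP targets 4 rose and 2 fell. Of the markers of other cell types Sox9 rose (1.02), a call that ended without control replicate 2 (0.90) and SRT1720 replicates 1 (1.11) or 2 (0.93). Adjusted over the list alone, 3 macrophage, 2 endothelial, 1 neural and 1 muscle marker also rose.

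SRT1720 plus RSL3 against RSL3 is the comparison to which the series title points, and it asks what SRT1720 changed in cells given RSL3. Hypoxia and glycolysis genes were lower with SRT1720, 23 of 29 down and 0 up in edgeR (25 down adjusted over the list alone, median -0.88, adjusted p = 0.00646 with an estimated correlation). Bnip3 went from 119.9 ± 3.47 to 16.8 ± 0.764 CPM (SD, n = 2; -2.84 ± 0.11, adjusted p = 1.8e-06). The pyruvate dehydrogenase kinase Pdk1 (-2.18 ± 0.13), the lactate transporter Slc16a3 (-2.46 ± 0.17) and the ankyrin-repeat gene Ankrd37 (-2.85 ± 0.25) also fell. Foxo3 went from 184.1 ± 24.6 to 60.9 ± 5.88 CPM (-1.60 ± 0.12, adjusted p = 8.69e-05) and Sirt1 from 105.0 ± 15.0 to 45.8 ± 4.86 CPM (-1.20 ± 0.13, adjusted p = 0.000343). Of 12618 genes 1442 rose and 1104 fell (20.2%), 379 and 310 of them by 2-fold or more. With library size only 1735 rose and 885 fell. The number called was 1091 without SRT1720 plus RSL3 replicate 1 and 846 without replicate 2.

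FOXO genes as a list were lower with SRT1720 in RSL3-treated cells, 13 of 32 down and 2 up (18 and 2 adjusted over the list alone, median -0.34, adjusted p = 0.0312 with an estimated correlation). Among them Ccng2 was at -2.62 ± 0.17 and the stress-response gene Sesn1 at -1.38 ± 0.15, while Gadd45a (0.84) and Cited2 (1.22) rose. Cholesterol genes were lower, 11 of 26 down (17 adjusted over the list alone, median -0.35, adjusted p = 0.0312 with an estimated correlation), with Insig1 going from 427.5 ± 23.1 to 144.3 ± 13.5 CPM (-1.57 ± 0.10) and the synthase Hmgcs1 at -1.03 ± 0.12. These 3 lists were the calls that held with an estimated correlation. NRF2 targets were lower with the preset correlation (8 of 31 down, the same adjusted over the list alone, median -0.24, adjusted p = 0.153 with an estimated correlation), with Nqo1 at -0.70 ± 0.11 and Ugdh at -0.80 ± 0.10. YAP targets were higher (8 of 19 up, 9 up and 1 down adjusted over the list alone, median 0.23, adjusted p = 0.153 with an estimated correlation). Ccn1 went from 399.7 ± 36.9 to 2344 ± 26.9 CPM (2.55 ± 0.10, adjusted p = 1.8e-06) and Ccn2 from 338.7 ± 36.2 to 1466 ± 126 CPM (2.11 ± 0.13). Extracellular matrix genes were lower, 16 of 45 down and 2 up (23 and 2 adjusted over the list alone, median -0.46, adjusted p = 0.645 with an estimated correlation), with the platelet-derived growth factor receptor gene Pdgfrb at -0.93 ± 0.13 and the lysyl oxidase Loxl2 at -0.79 ± 0.12. The call of the matrix list ended without RSL3 replicate 2 (-0.24), the library in which the list was 0.35 higher than in RSL3 replicate 1.

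Heat shock and ATF4 genes did not pass as lists in this comparison. Of 23 heat shock genes 4 fell and 1 rose (7 and 1 adjusted over the list alone, median -0.12), and of 41 ATF4 targets 6 fell and 3 rose (the same adjusted over the list alone), with Atf3 at -0.97 ± 0.10 and Ddit4 at -1.24 ± 0.11. The ATF4 median was -0.004 and was 0.05 with library size only. Chac1 was at 940.2 ± 68.7 CPM (-0.03 ± 0.10, adjusted p = 0.854) and Ptgs2 at 1441 ± 171 CPM (-0.08 ± 0.13, adjusted p = 0.693), and neither passed. Hmox1 was at 5630 ± 70.5 CPM (-0.58 ± 0.24, adjusted p = 0.117), Gpx4 at 369.6 ± 23.2 CPM (-0.02 ± 0.12, adjusted p = 0.947), Acsl4 at 47.97 ± 4.59 CPM (-0.23 ± 0.12, adjusted p = 0.228) and Cpt1a at 25.1 ± 0.150 CPM (-0.32 ± 0.14, adjusted p = 0.135). Scd1 did not pass at 109.7 ± 10.0 CPM (-0.41 ± 0.13, adjusted p = 0.0502), while its paralog Scd2 fell from 386.8 ± 14.3 to 158.7 ± 11.9 CPM (-1.29 ± 0.09, adjusted p = 5.57e-05). Hmox1 passed without control replicate 1 (-0.58) or 2 (-0.58), and Scd1 without control replicate 1 (-0.41) or 2 (-0.41) and RSL3 replicate 1 (-0.51). Slc7a11 fell to 54.0 ± 8.29 CPM (-0.77 ± 0.14, adjusted p = 0.00539), a call that ended without SRT1720 plus RSL3 replicate 2 (-0.62).

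The remaining lists did not pass between SRT1720 plus RSL3 and RSL3. Immediate early genes had 14 members down and 9 up of 40 (15 and 9 adjusted over the list alone, median -0.23), with Zfp36 at -2.14 ± 0.11 and the phosphatase Dusp6 at 1.75 ± 0.14. NF-kB genes had 6 up and 1 down of 27 (6 and 2 adjusted over the list alone, median 0.31), with Tnfaip3 at 2.16 ± 0.17. Ferroptosis suppressors had 7 down and 1 up (8 and 1 adjusted over the list alone, median -0.18), and drivers 3 of each (7 down and 3 up adjusted over the list alone). Fatty acid synthesis had 3 down and 2 up (4 and 2 adjusted over the list alone), with the elongase Elovl6 at -0.94 ± 0.16. Fatty acid activation had 4 down and 2 up (4 and 1 adjusted over the list alone), with the acyltransferase Mboat2 at -1.12 ± 0.19 and Lpin1 at -0.93 ± 0.15. In fatty acid oxidation 2 genes fell and 1 rose (1 down adjusted over the list alone), and among PPAR genes 2 fell and 1 rose, with Acot2 at 1.39. Unfolded protein response genes had 3 down and 1 up, metallothionein genes 2 and 1 (3 and 1 adjusted over the list alone), iron-handling genes 2 of each, p53 targets 4 of each, cell cycle genes 5 down and 4 up, and sirtuin genes 3 down and 2 up (4 and 3 adjusted over the list alone), with Nampt at -0.99 ± 0.13. Medians and tests differed in sign for the sirtuin (0.05), fatty acid activation (0.05), p53 (-0.04) and cell cycle (0.01) lists. Among single genes with large rises were H2ac24 (2.47 ± 0.14), Trmt12 (2.69 ± 0.24) and Riox1 (2.29 ± 0.13). Of the markers of other cell types the endothelial Kdr (0.79) and Cdh5 (1.82), the epithelial Grhl2 (2.05), the muscle gene Tnnt2 (1.24) and Sox9 (0.61) rose, the neural Tubb3 fell (-0.63) and 0 macrophage genes passed in edgeR (4336 genes had an unadjusted p under 0.05). All 6 calls ended without SRT1720 plus RSL3 replicate 2 (0.89, 1.83, 1.83, 1.20, 0.61 and -0.63), and those of Kdr (0.68), Cdh5 (1.83), Sox9 (0.62) and Tubb3 (-0.615) without replicate 1. That of Kdr also ended without SRT1720 replicate 1 (0.79) or 2 (0.79), RSL3 replicate 1 (0.74) or 2 (0.85), with the 4 libraries compared on their own (0.78) and with DESeq2 (0.79).

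**Figure D2:**
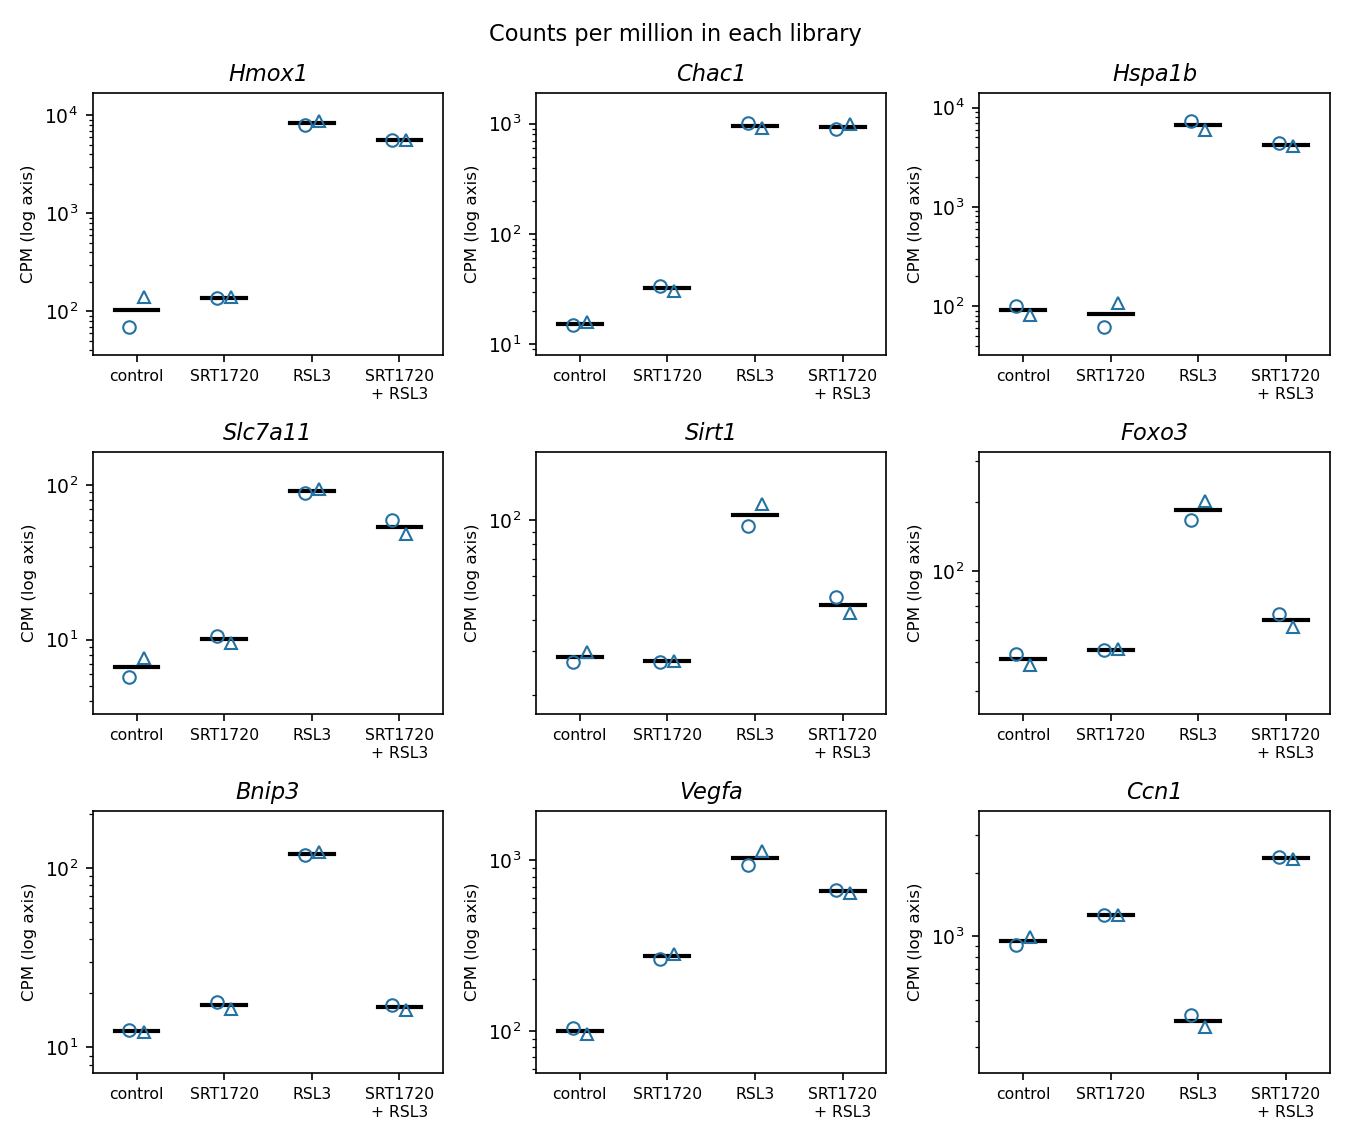
Level of 9 genes in CPM on a log axis in each of the 8 libraries, with circles for replicate 1, triangles for replicate 2 and bars for the mean of 2. Bnip3 stood at 119.9 CPM with RSL3 alone and 16.8 CPM with SRT1720 and RSL3, Chac1 at 961.3 and 940.2 CPM, and Ccn1 at 399.7 and 2344 CPM.

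SRT1720 plus RSL3 against SRT1720 gives the effect of RSL3 in cells that had received SRT1720, from libraries that the first comparison does not use. The stress genes rose here too. Hmox1 went from 138.4 ± 2.28 to 5630 ± 70.5 CPM (SD, n = 2; 5.35 ± 0.29), Chac1 from 32.2 ± 2.45 to 940.2 ± 68.7 CPM (4.87 ± 0.12, adjusted p = 2.3e-08), Slc7a11 was at 2.43 ± 0.16, Ptgs2 at 2.08 ± 0.14 and Hspa1a at 6.73 ± 0.23. Of 12618 genes 1549 rose and 1143 fell (21.3%), 390 and 251 of them by 2-fold or more, and with library size only 894 rose and 3066 fell, a shift of -0.21. The number called was 1041 and 1263 without SRT1720 replicates 1 and 2, and 1154 and 1233 without SRT1720 plus RSL3 replicates 1 and 2. With the 4 libraries compared on their own, 4682 genes were called here and 2931 in RSL3 against control. That order is the reverse of the order with all 8 libraries, so these counts do not rank the 2 effects by size. After RSL3 in SRT1720 cells, heat shock genes had 23 of 23 up (median 1.30). ATF4 targets had 37 of 41 up and 1 down (38 and 1 adjusted over the list alone, median 1.33). Immediate early genes had 31 of 40 up (32 adjusted over the list alone, median 1.60). NRF2 targets had 12 of 31 up (14 up and 1 down adjusted over the list alone, median 0.37), with Gclm at 1.24. FOXO genes had 18 up and 2 down (19 and 3 adjusted over the list alone, median 0.46), with Irs2 at 1.47, p53 targets 11 and 3 (11 and 4 adjusted over the list alone, median 0.32), and ferroptosis suppressors 13 and 1 (15 and 1 adjusted over the list alone, median 0.35). These 7 lists held with an estimated correlation. Unfolded protein response genes (5 of 22 up, median 0.18, or -0.03 with library size only, adjusted p = 0.449 with an estimated correlation), metallothionein genes (4 up and 1 down, adjusted p = 0.196 with an estimated correlation) and cell cycle genes (21 of 39 down and 9 up, median -0.37, adjusted p = 0.185 with an estimated correlation) passed with the preset correlation only. Adjusted over the list alone they had 7 up and 1 down, 4 up and 1 down, and 24 down and 10 up. The metallothionein call also ended without SRT1720 replicate 2 (1.20).

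Hypoxia genes did not pass as a list after RSL3 in SRT1720 cells, with 5 of 29 up and 2 down (median 0.07, or -0.14 with library size only, adjusted p = 0.0845). Vegfa (1.27 ± 0.11) and Ndrg1 (1.81) rose, while Bnip3, chosen after its values were seen, was at 17.1 ± 1.22 CPM with SRT1720 and 16.8 ± 0.764 CPM with both (-0.03 ± 0.11, adjusted p = 0.87). Cholesterol genes had 3 up and 4 down (4 and 7 adjusted over the list alone, median -0.10), with Insig1 at 1.10. Sirt1 rose (0.75 ± 0.13, adjusted p = 0.00324), and Foxo3 passed at 0.43 ± 0.12 (adjusted p = 0.0351). The call of Foxo3 ended with library size only (0.22) and without SRT1720 replicate 1 (0.42), SRT1720 replicate 2 (0.43), SRT1720 plus RSL3 replicate 1 (0.32) or replicate 2 (0.52). Gpx4 (0.05), Acsl4 (0.02), Cpt1a (-0.20) and Scd1 (-0.26) did not pass, although Scd1 did with library size only (-0.46), while Scd2 (-1.06 ± 0.09) and Elovl6 (-1.06) fell. The lists of drivers (7 up, 2 down), iron handling (3, 3), fatty acid oxidation (1, 4), PPAR genes (2, 1), fatty acid synthesis (2, 3), fatty acid activation (5, 3), sirtuins (2, 0), matrix genes (4, 2), NF-kB genes (5, 10) and YAP targets (4, 2) did not pass. Median and mean differed in sign for iron handling (-0.004 and 0.20), matrix (-0.04 and 0.02) and YAP genes (-0.11 and 0.25), and the test went up for all 3.

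Of the 4511 genes that RSL3 changed without SRT1720, 86.5% moved in the same direction in SRT1720 cells, and the median ratio of the change with SRT1720 to that without was 0.505. In 20 simulations with additive effects that ratio was 0.881 (0.871 to 0.894) and 97.78% moved in the same direction. In 20 simulations in which SRT1720 kept its effect in cells without RSL3 and had none in RSL3-treated cells, the ratio was 0.689 (0.674 to 0.706) and 91.28% moved in the same direction. Taken the other way, from the genes called in SRT1720 cells, 92.05% moved in the same direction and the ratio was 0.937 (0.881 in simulation). Up in both comparisons were 1105 genes, where 283 would be shared if calls were independent, and down in both were 780 against 200. Independence is a low bar for 2 comparisons of the same compound. In either direction 1885 genes were shared, fewer than the 2632 (2597 to 2731) of the additive simulations and the 2429 (2379 to 2485) of the others. Those simulations also called more genes in SRT1720 cells (3796 and 3711) than the data did (2692). The ratio differed between lists. The members that rose after RSL3 had a median ratio of 0.977 for ATF4 targets (37 genes), 0.917 for heat shock (22), 0.738 for p53 targets (13), 0.687 for immediate early genes (33), 0.687 for suppressors (16), 0.635 for NRF2 targets (22), 0.599 for FOXO genes (20), 0.431 for the unfolded protein response (14), 0.204 for cholesterol genes (15) and 0.138 for hypoxia genes (26). Of the 4511 genes 74.6% moved the opposite way between RSL3 and SRT1720 plus RSL3, 1449 of them past the threshold, and 157 passed in the same direction. RSL3 against control and SRT1720 plus RSL3 against RSL3 share the RSL3 libraries with opposite sign, so opposite movement also arises by chance. In the simulations without an effect of SRT1720 in RSL3-treated cells 59.53% (58.27% to 61.62%) moved the opposite way. A median of 0 (0 to 2) of them passed the threshold. Those simulations gave all groups the same spread, while the RSL3 pair differed most here (SD of the log2 difference 0.275). Opposite movement by chance may thus be more frequent than simulated. With additive effects a median of 396.5 genes (346 to 443) passed in the opposite direction and 198.5 (173 to 226) in the same.

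**Figure D3:**
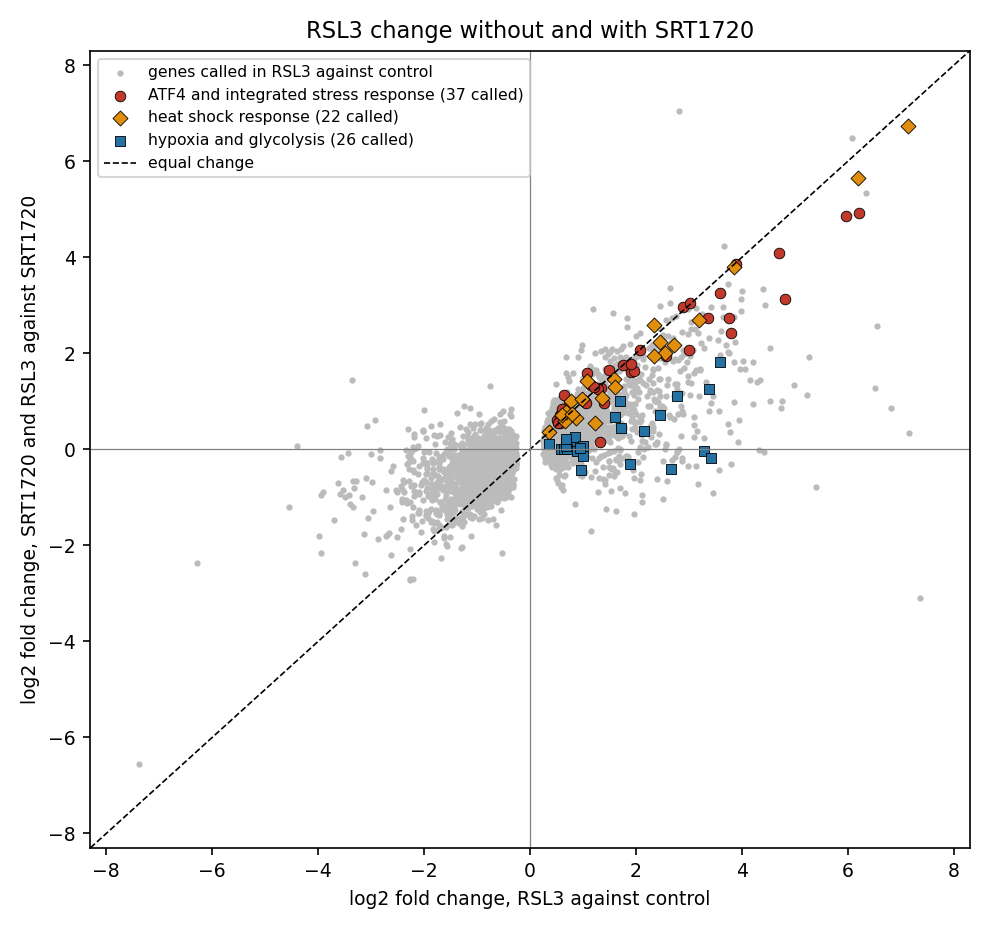
Log2 fold change of the 4511 genes changed by RSL3 against control (x axis) and of the same genes between SRT1720 plus RSL3 and SRT1720 (y axis), with 2 libraries per group and a dashed line at equal change; red circles are ATF4 targets (37), orange diamonds heat shock genes (22) and blue squares hypoxia genes (26). ATF4 targets lay near the line with a median ratio of 0.977, and hypoxia genes below it at 0.138.

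SRT1720 plus RSL3 against control sets the cells with both compounds beside untreated ones. Hmox1 rose by 5.76 ± 0.29 on the log2 scale, Chac1 by 5.94 ± 0.13, Slc7a11 by 3.02 ± 0.16 and Atf3 by 5.24 ± 0.12 (n = 2 per group). The largest falls included those of Nynrin (-2.82), Chst12 (-2.74), Inhbb (-2.68) and Haspin (-2.38). Sirt1 rose (0.69 ± 0.13, adjusted p = 0.00323), and so did Foxo3 (0.56 ± 0.12, adjusted p = 0.00723). The call of Foxo3 ended with library size only (0.34) and without control replicate 2 (0.48) or SRT1720 plus RSL3 replicate 1 (0.46). Gpx4 (0.27), Acsl4 (0.15), Cpt1a (-0.38) and Scd1 (-0.30) did not pass, but Cpt1a did with library size only (-0.61) or without control replicate 2 (-0.53) or RSL3 replicate 1 (-0.38) or 2 (-0.38), and Scd1 did with library size only (-0.53) or without RSL3 replicate 1 (-0.31) or 2 (-0.30). Scd2 fell from 353.4 ± 8.85 to 158.7 ± 11.9 CPM (-1.16 ± 0.09). Of 12618 genes 2191 rose and 1780 fell (31.5%), 664 and 375 of them by 2-fold or more, and with library size only 1290 rose and 4017 fell, a shift of -0.23. Without control replicate 2 the number called was 2596, and without SRT1720 plus RSL3 replicates 1 and 2 it was 2286 and 2047. Heat shock (23 of 23 up, median 1.29), ATF4 (38 of 41 up, median 1.56), immediate early (34 up and 1 down of 40, median 1.69), NRF2 (17 of 31 up, median 0.41), FOXO (16 up and 4 down of 32, median 0.44), p53 (12 up and 4 down of 23, median 0.64) and suppressor genes (14 up and 2 down of 31, median 0.30) passed as lists and held with an estimated correlation. Adjusted over the list alone the members up were 23, 39, 35, 17, 20, 14 and 15. Fatty acid oxidation genes were lower (9 of 35 down and 1 up, the same adjusted over the list alone, median -0.25, adjusted p = 0.179 with an estimated correlation), with Gpam (-1.57), a glycerol-phosphate acyltransferase of the phospholipid list, and Cpt2 (-0.91) among the genes that fell. Cell cycle genes were lower (23 of 39 down and 9 up, adjusted p = 0.112 with an estimated correlation). Hypoxia genes were higher (11 of 29 up and 2 down, median 0.19, or -0.03 with library size only, adjusted p = 0.0627 with an estimated correlation), as were unfolded protein response genes (9 up and 1 down, adjusted p = 0.277 with an estimated correlation) and metallothionein genes (4 up and 1 down, adjusted p = 0.095 with an estimated correlation). Drivers (8 up, 4 down), iron handling (5, 2), PPAR (5, 2), fatty acid synthesis (3, 4), fatty acid activation (13, 2), cholesterol (10, 4), sirtuin (4, 1), matrix (7, 8), NF-kB (10, 6) and YAP genes (4, 4) did not pass as lists. For fatty acid synthesis the median (0.17) and the test differed in sign.

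The interaction tests whether the effect of RSL3 differed with SRT1720. Bnip3 rose after RSL3 alone (3.28 ± 0.11) and not after SRT1720 and RSL3 (-0.03 ± 0.11), an interaction of -3.31 ± 0.15 (adjusted p = 1.98e-05). Foxo3 had an interaction of -1.73 ± 0.17 (adjusted p = 0.000786), Vegfa of -2.11 ± 0.16, Insig1 of -2.35 ± 0.15 (adjusted p = 8.3e-05), Scd2 of -1.19 ± 0.13 (adjusted p = 0.00108) and Chac1 of -1.11 ± 0.15 (adjusted p = 0.00357). Ccn1 went the other way at 2.15 ± 0.13 (adjusted p = 8.3e-05). Sirt1 was at -1.14 ± 0.18 (adjusted p = 0.00733), a call that ended without SRT1720 replicate 1 (-1.14) and without SRT1720 plus RSL3 replicate 2 (-1.03). Slc7a11 was at -1.36 ± 0.22 (adjusted p = 0.0077), which ended without SRT1720 replicate 1 (-1.29). Ptgs2 was at -1.01 ± 0.19 (adjusted p = 0.0133), which ended without SRT1720 replicate 1 (-0.97), SRT1720 replicate 2 (-1.04) or SRT1720 plus RSL3 replicate 2 (-0.89). Hmox1 did not pass (-0.99 ± 0.34, adjusted p = 0.123), but did without control replicate 2 (-1.58). Gpx4 (-0.24), Acsl4 (-0.36), Cpt1a (-0.14) and Scd1 (-0.36) did not pass. Chac1 and Ptgs2 did not pass between SRT1720 plus RSL3 and RSL3, and both rose with SRT1720 alone. Their interaction thus came mostly from a higher level without RSL3. Vegfa also rose with SRT1720 alone, which made up the larger part of its interaction. Of 12618 genes 436 were positive and 368 negative (6.4%), 207 and 189 of them by 2-fold or more, and with library size only 600 and 284. The number called was 183 and 256 without SRT1720 replicates 1 and 2, 271 and 227 without SRT1720 plus RSL3 replicates 1 and 2, 477 without control replicate 2 and 1247 without RSL3 replicate 1. In 20 additive simulations, which hold no interaction, the median number called was 1 (0 to 3). In the 20 simulations in which SRT1720 acted only in cells without RSL3, which is itself an interaction, it was 235 (186 to 316). Both kinds drew the counts of each gene alone and with the same spread in all groups. They lack the deviations that genes of a library shared here, so calls without an interaction may be more frequent than simulated.

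By list, the interaction was negative for hypoxia genes (20 of 29 down, 23 adjusted over the list alone, median -0.91, adjusted p = 0.00327 with an estimated correlation), cholesterol genes (10 of 26 down, 14 adjusted over the list alone, median -0.44, adjusted p = 0.0127 with an estimated correlation), FOXO genes (11 of 32 down and 1 up, 13 and 2 adjusted over the list alone, median -0.35, adjusted p = 0.0162 with an estimated correlation) and immediate early genes (16 of 40 down and 5 up, 20 and 8 adjusted over the list alone, median -0.71, adjusted p = 0.0493 with an estimated correlation). Other calls did not hold with an estimated correlation. NRF2 targets had 3 of 31 down (10 adjusted over the list alone, median -0.24, adjusted p = 0.064 with an estimated correlation). YAP targets had 4 of 19 up (6 adjusted over the list alone, median 0.34), suppressors 3 of 31 down (8 adjusted over the list alone, median -0.12) and fatty acid synthesis genes 1 of 29 down (1 adjusted over the list alone, median -0.19), each with adjusted p = 0.133 with an estimated correlation. Unfolded protein response genes had 2 down (2 adjusted over the list alone, median -0.28, adjusted p = 0.448 with an estimated correlation), metallothionein genes 2 down (2 adjusted over the list alone, median -0.25, adjusted p = 0.154 with an estimated correlation) and ATF4 targets 6 down (8 adjusted over the list alone, median -0.03, or 0.04 with library size only, adjusted p = 0.596 with an estimated correlation). The ATF4 call ended without control replicate 1 (0.03) or RSL3 replicate 1 (0.004), that of metallothionein genes without control replicate 1 (-0.24) and that of suppressors without SRT1720 replicate 2 (-0.16). Drivers (2 down), heat shock (1 down), iron handling (1 down), fatty acid oxidation (1 down), PPAR (1 up, 1 down), fatty acid activation (2 down), sirtuin (3 down), matrix (1 up, 2 down), NF-kB (1 up, 3 down), p53 (1 up, 3 down) and cell cycle genes (1 down) did not pass as lists. For the sirtuin list the median (0.13) differed in sign from the mean (-0.12) and the test.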

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

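The tests by removal of GC and length trends and by the share of the RSL3 change that different lists kept were chosen only after the result was seen. For these results the effect of RSL3 differed between cells with and without SRT1720 by the interaction test, taken for lists at the preset correlation. Several of these list calls did not hold with an estimated correlation. By gene, the interaction test passed for 804 of 12618 genes.

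Hypoxia and glycolysis genes were the list with the most negative interaction (median log2 change -0.91), with Ankrd37 at -3.60, Bnip3 at -3.31 and Slc16a3 at -3.06. Trends on GC content and transcript length are argued against, since the median was -0.97 with them removed, and so is a single deviating library, since without each of the 8 libraries in turn it lay between -0.997 and -0.875, beyond the limit of -0.45 that was set before these values were computed. The 26 members that rose kept a median share of 0.138 of their change (95% bootstrap interval 0.007 to 0.292). The 2282 other genes that rose kept 0.566 (quartiles 0.25 and 0.869, one-sided permutation p = 5e-04, the smallest that 2000 permutations can give). This share restates the interaction by which the list was picked, and the permutation makes no allowance for that choice. The test therefore cannot decide whether a general weakening of the RSL3 response is the cause. The share was also low for cholesterol genes (0.204) and, less so, for the unfolded protein response (0.431). Above the 0.566 of the other genes that rose were FOXO genes (0.599), NRF2 targets (0.635), immediate early genes and ferroptosis suppressors (0.687 each) and p53 targets (0.738). Heat shock genes (0.917) and ATF4 targets (0.977) kept most of their change. Over all 4511 genes that RSL3 changed, up or down, the median was 0.505. A difference in culture density or oxygen that goes with the group cannot be told apart from the treatment, because there are 2 libraries per group and the labels give no plate or day. An effect of SRT1720 on the hypoxia response to RSL3 is a hypothesis that these data may hold, and with a technical explanation open it is not called biological.

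The list medians of the interaction were -0.44 for cholesterol synthesis, -0.35 for FOXO genes, -0.71 for immediate early genes, -0.24 for NRF2 targets, -0.28 for the unfolded protein response, -0.25 for metallothionein genes, -0.19 for fatty acid synthesis, -0.12 for ferroptosis suppressors, -0.032 for ATF4 targets (0.04 with library size only) and 0.34 for YAP targets. Of these, the cholesterol, FOXO and immediate early lists held with an estimated correlation and the others did not. Among the always-named genes Foxo3 was at -1.73, Slc7a11 at -1.36, Sirt1 at -1.14, Chac1 at -1.11 and Ptgs2 at -1.01. Chac1 and Ptgs2 rose with SRT1720 alone and did not pass between SRT1720 plus RSL3 and RSL3. The other negative values were -3.51 for Gem, -3.33 for Nr4a2, -2.72 for Ccng2, -2.72 for Rnf225 and -2.48 for Cdk5r1. The positive values were 2.92 for H2ac24, 2.82 for Edn1, 2.62 for Trmt12, 2.41 for Riox1, 2.31 for Ddx28, 2.25 for Pars2, 2.25 for Lcmt2 and 2.15 for Ccn1.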

How the results depend on the processing

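Removal of GC and length trends, the crossed replicate block and the omission of both libraries numbered 2 of control and RSL3 were chosen only after the data had been seen. Of 896 list results under alternatives, from 64 main ones, 842 kept their direction and side of the threshold and 54 no longer passed, 34 of these with the estimated correlation. Of 9805 results for named genes, from 549 main ones, 9176 kept both, 517 no longer passed, 83 passed only under the alternative and 29 reversed. A library left out leaves a lone library that is assumed to vary like the other groups. The 4 libraries on their own cannot give the interaction, and list tests were not run with library size only, limma-voom, DESeq2, the unfiltered table or the 4 libraries on their own. List medians with library size only were computed and are not among the 896. For all values in this part the cause was not tested. At this depth and with 2 libraries per group, 48% of 1.5-fold and 86% of 2-fold changes were recovered in simulated data. Genes with the lowest counts were not among those altered there.

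With the 4 libraries compared on their own, RSL3 against control called 2931 genes, SRT1720 plus RSL3 against RSL3 1578 and against SRT1720 4682. SRT1720 against control called 286 genes in that way, 500 with the crossed replicate block, 331 with GC and length trends removed, 394 without both libraries numbered 2 and 384 with DESeq2. SRT1720 plus RSL3 against SRT1720 called 4589 genes without both libraries numbered 2. The interaction called 1341 genes with the crossed block, 1248 with GC and length trends removed and 1224 without both libraries numbered 2. Without each library in turn the counts ranged from 9 to 511 for SRT1720 against control, from 846 to 3482 for SRT1720 plus RSL3 against RSL3, from 1041 to 3542 against SRT1720, from 2047 to 4940 against control and from 183 to 1247 for the interaction. The median ratio of the RSL3 effects was 0.557 with library size only and 0.441 to 0.519 without single libraries. The share of genes moving the opposite way was 79.2% with a minimum of 1.5-fold, 76.8% without both libraries numbered 2, 77.7% in the 4 libraries on their own and 74.1% to 79.2% without single libraries.

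Reversals fell on genes that had not passed. With library size only they were Scd1 in RSL3 against control (-0.18), Acsl4 in SRT1720 plus RSL3 against control (-0.076) and against SRT1720 (-0.18), Gpx4 against SRT1720 (-0.16) and against RSL3 (0.041), and Chac1 against RSL3 (0.024). With GC and length trends removed, Gpx4 was at -0.055 against SRT1720. Without both libraries numbered 2, Scd1 (0.10) and Sirt1 (0.004) reversed in SRT1720 against control, Ptgs2 in SRT1720 plus RSL3 against RSL3 (0.12) and Cpt1a in the interaction (0.15). Without single libraries Cpt1a in RSL3 against control ranged from -0.21 to 0.12 and Scd1 from -0.036 to 0.25. In SRT1720 against control Hmox1 ranged from -0.006 to 1.01, Scd1 from -0.18 to 0.10 and Sirt1 from -0.13 to 0.005. In SRT1720 plus RSL3 against RSL3 Chac1 ranged from -0.11 to 0.068, Gpx4 from -0.15 to 0.15 and Ptgs2 from -0.24 to 0.12. Against SRT1720 Acsl4 ranged from -0.081 to 0.12 and Gpx4 from -0.024 to 0.13, and in the interaction Cpt1a ranged from -0.32 to 0.011.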

Other observations

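The tests of the added lists and the genes named from them, the removal of GC and length trends with its change over the same genes, the percent down minus the percent up of genes with 1 exon, the loss of genomic or unspliced reads in the less abundant genes alone and the comparison of upstream with divergent neighbours were chosen only after the result was seen, and the share of upstream neighbours at 50 CPM was computed after that at 20 CPM had been seen. Of 31 proteasome subunit genes 12 rose after RSL3 (median 0.25, or -0.03 with library size only) and 11 in SRT1720 cells (median 0.26), with adjusted p = 0.593 and 0.626 with an estimated correlation. Of 28 interferon-stimulated genes 10 fell after RSL3 (median -0.51) and 11 in SRT1720 cells (median -0.57), with adjusted p = 0.602 and 0.626 with an estimated correlation. Among them Ifit1 was at -2.27 ± 0.36 in RSL3 against control (n = 2 per group).

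Zinc finger genes with Zfp symbols, most of which encode transcription factors, moved down after RSL3, with 157 of 344 down and 28 up (median -0.51, adjusted p = 0.092 with an estimated correlation). In SRT1720 cells 47 fell and 44 rose after RSL3 (median -0.07), and between SRT1720 plus RSL3 and RSL3 137 rose and 16 fell (median 0.49, adjusted p = 0.108 with an estimated correlation). The interaction passed as positive for 62 of them and as negative for 3 (median 0.48, adjusted p = 0.0841 with an estimated correlation). Among 24 actin cytoskeleton genes 6 fell and 2 rose after RSL3, and 7 rose with SRT1720 in RSL3-treated cells (adjusted p = 0.593 and 0.35 with an estimated correlation). The beta-actin gene Actb fell by 1.25 on the log2 scale after RSL3 (SE 0.09), rose with SRT1720 in RSL3-treated cells (0.97 ± 0.09) and had an interaction of 1.15 ± 0.13. Among 6 genes of the aryl hydrocarbon receptor pathway, 3 fell and 2 rose with SRT1720 alone (median -0.80, adjusted p = 0.0813 with an estimated correlation). Cyp1b1, a cytochrome P450 gene induced by that receptor, fell from 2.87 to 0.111 CPM (-4.62 ± 0.54, adjusted p = 0.00555), and the receptor gene Ahr rose (1.03 ± 0.16, adjusted p = 0.0165). Both levels of Cyp1b1 lie under the mean of 5 CPM asked of the genes with the largest changes. Values of these 2 genes under the alternatives are not given here, and many calls of this comparison ended without 1 SRT1720 library.

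Genes with 1 exon fell more often than others after RSL3, and they also rose more often. Of 271, 91 were down (33.6%) and 61 up (22.5%), against 17.2% down and 18.3% up of 12131 genes with more exons. Their median was -0.19 against -0.01 in genes of like abundance, a difference of -0.18 (95% bootstrap interval -0.343 to 0.061, one-sided permutation p = 5e-04, the smallest that 2000 permutations can give), and the difference was 0.02 after RSL3 in SRT1720 cells. GC and length trends are argued against as the whole cause. With them removed the difference was -0.17 (interval -0.337 to 0.063, one-sided permutation p = 5e-04), and over the same genes the removal changed it by 0.017 (95% bootstrap interval -0.079 to 0.038), less than the 0.09 that would take away 50% of it. Loss of genomic or unspliced reads would lower the less abundant genes most, and it is argued against as the whole cause. The difference was -0.35 in genes above the median of 26 CPM (62 genes, interval -0.523 to 0.114, one-sided permutation p = 5e-04) and -0.09 in those below it (209 genes, interval -0.302 to 0.148, one-sided permutation p = 0.047). Above the median 45.2% fell and 30.6% rose, against 14.3% and 26.1% of genes of like abundance with more exons. The percent down minus the percent up was thus larger by 26.3 (95% bootstrap interval 4.8 to 46.4, one-sided permutation p = 0.001). By this measure it was larger by 9.1 over all 271 genes (interval -0.2 to 17.6, one-sided permutation p = 0.0045). Below the median it was larger by 3.9 (interval -5.6 to 13.4, one-sided permutation p = 0.15). The value above the median also argues against a few abundant genes taking a larger share of the counts as the cause in those 62 genes. Over all 271 genes that cause cannot be told apart (difference -0.18, with an interval that includes 0), nor can loss of such reads in the less abundant genes, whose interval includes 0 too. No biological explanation was tested.

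After RSL3, 267 genes with a mean under 5 CPM rose by 2-fold or more, and reads running on from a neighbouring gene may contribute. An expressed gene lay upstream on the same strand within 10 kb for 18.7% of them (50, exact 95% interval 14.2 to 23.9) and for 7.4% of the other 2494 low-abundance genes (Fisher's exact test, p = 1.94e-08). Reads from such neighbours, at 50 CPM or more in control, are thus argued against as the cause for most of them, and a part is left open. Neighbours below that level in control that RSL3 itself raised, and those beyond 10 kb, were not counted. Whether reads ran on from these cannot be told. The prediction had set no level for an expressed neighbour: 50 CPM in control was intended, but 20 CPM was run first in error and gave 28.1% (22.8 to 33.9) against 11.3% (Fisher's exact test, p = 4.16e-12). Low-abundance genes with such an upstream neighbour had a median log2 change of 0.31 (188 genes) against -0.06 with a divergent one (72 genes; one-sided permutation p = 0.0062) in RSL3 against control, and -0.28 in SRT1720 plus RSL3 against SRT1720. Reads shared with an overlapping gene are argued against as the main cause, since 16.1% of the genes that rose overlapped another gene (11.9 to 21.1) against 19.2% of the others (Fisher's exact test, p = 0.25).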
